A study of Mus musculus with 21 samples.

How the data were processed

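The data were microarray measurements of gene expression in mouse embryonic pancreas, sorted by the Foxa2-Venus fusion into FVF+ and FVF- cells at E12.5, E13.5, E14.5 and E15.5, with 2 or 3 arrays per sort and day and 21 in all. Per the labels' protocols, RNA was purified with a Qiagen RNeasy Mini kit, amplified with the Ambion WT Expression kit and labelled with Affymetrix WT reagents. Per the submitters' processing notes, the authors summarised the arrays by robust multi-array average (RMA) with affy 1.44.0, and the deposited values are on a log2 scale. How probe sets were defined and which were left out is not given in the sources used here. Raw intensities were not analysed here, and the values were used as deposited.

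The value table held 23305 probe sets, with values from 4.0 to 15.31 and array medians from 8.68 to 8.82. The platform annotation gave exactly 1 gene symbol to 20728 probe sets, several symbols to 1174 and none to 1403. Symbols were checked against the reference gene table by Entrez identifier: 0 were updated, and 43 identifiers were not in the reference. For the 804 genes with more than 1 probe set, the one with the highest mean over all arrays was used, which left 19296 genes. No gene is named from a probe set with several symbols.

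A linear model with 8 group means was fitted to all 21 arrays in limma 3.58.1 under R 4.3.3, with 13 residual degrees of freedom, and moderated by empirical Bayes. P-values were two-sided, adjusted by Benjamini and Hochberg over all 19296 genes within each comparison, and a gene was called at an adjusted p under 0.05. All adjusted p-values for genes are from limma. Errors given with a log2 difference are the moderated standard errors (SE), and errors given with a group mean are standard deviations (SD). There were 14 comparisons: FVF+ against FVF- within each day and as the mean of the 4 daily differences, E15.5 against E12.5 and each daily step within either sort, and the interaction of sort with the change from E12.5 to E15.5. Counts expected of independent lists are products of the shares called.

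Before the data were examined, 20 gene lists, the comparisons, the threshold, most alternatives and the rule for naming genes were fixed. The lists covered progenitor transcription factors (16 of 18 members measured), epithelial genes (24 of 24), endocrine lineage genes (20 of 23), hormone and granule genes (26 of 30), acinar genes (28 of 32), ductal genes (16 of 19), mesenchyme (32 of 32), smooth muscle (12 of 12), mesothelium (8 of 9), endothelium (20 of 20), red blood cell lineage (14 of 20), macrophages and leukocytes (22 of 22), neural crest, glia and neurons (17 of 22), neighbouring organs (18 of 18), cell cycle (29 of 30), Notch (20 of 20), Wnt and planar cell polarity (25 of 25), basement membrane and integrins (20 of 20), immediate early and heat shock genes (18 of 20), and X-inactivation and Y-linked genes (4 of 5). The last served as a check of the mix of embryos and was not tested as a set. The other 19 were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the residuals and with fry. Camera sets the members of a list against all other genes, whereas fry asks only whether the members changed. Fry p-values are given for the mean sort difference. Some genes are members of several lists.

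Named genes were the 8 with the largest rise and the 8 with the largest fall among called genes whose arrays did not overlap between groups (no overlap rule for the interaction), up to 4 called members per direction and up to 2 members not called from each list, Foxa2, and the 3 largest rises and falls of each day or step, passing over predicted genes. Alternatives were a 2-fold threshold, all probe sets, the mean of a gene's probe sets, a filter on dim genes (11407 genes with a group mean above 8.77), median centring, quantile normalization, an intensity trend with robust moderation, array weights, fits on single comparisons, blocks by replicate number, a term for letter-coded arrays, the days without E13.5, and leaving out each array. Cyclic loess normalization and leaving out a pair of E14.5 arrays were chosen after seeing the data.

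The steps were tested on simulated data with the same groups. Of genes shifted by 1 log2 unit, 100% were called for the mean sort difference, 92.5% for the change in FVF+, 94.0% for the change in FVF- and 79.1% for the interaction, and of genes shifted by 0.5 log2 units, 89.4%, 53.0%, 39.4% and 7.58%. Of unchanged genes, at most 0.0628% were called. In each simulation 19096 of the 19296 genes were unchanged, whereas these comparisons called 3786 to 10744 genes in the data. The adjusted threshold depends on the share of changed genes, so these percentages are not rates for the measured data. Camera called 0 of 20 lists of unchanged genes and the 1 list of shifted genes. The simulated genes varied independently of each other, so this does not show how camera at its preset correlation treats correlated genes. Members of the measured lists had estimated correlations of 0.072 to 0.772.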

Results

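Gene expression was measured by Affymetrix array in cells sorted from the mouse embryonic pancreas at E12.5, E13.5, E14.5 and E15.5. The sort was on FVF, a fusion of Foxa2, a forkhead transcription factor of the endoderm, with the fluorescent protein Venus. Cells that carried the fusion protein are called FVF+ here and the remaining pancreatic cells FVF-. There were 2 FVF- and 3 FVF+ arrays at E12.5, 2 of each at E13.5, and 3 of each at E14.5 and at E15.5, 21 in all. The design text speaks of biological replicates without saying whether they came from separate embryos, litters or sorts, so p-values measure the spread between these samples, and the number of arrays limits the precision. Values were log2 RMA signals, and 19296 named genes were tested. Arrays of one group correlated at 0.985 to 0.997 over genes, and arrays of different sorts at 0.889 to 0.941. The first principal component held 69.4% of the variance and separated the sorts, with every FVF+ array at 39.7 or above and every FVF- array at -49.2 or below. The second held 13.2%.

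The Foxa2 transcript was higher in FVF+ cells on every day. Its group means in FVF+ were 11.19 ± 0.09 at E12.5 (SD, n = 3), 11.13 ± 0.09 at E13.5 (n = 2), 11.31 ± 0.18 at E14.5 (n = 3) and 11.09 ± 0.26 at E15.5 (n = 3). In FVF- they were 8.18 ± 0.11 (n = 2), 8.15 ± 0.06 (n = 2), 8.47 ± 0.42 (n = 3) and 8.26 ± 0.29 (n = 3). The log2 difference in Foxa2 averaged over the 4 days was 2.91 ± 0.10 (SE, limma adjusted p = 1.9e-14). Between E12.5 and E15.5, Foxa2 differed by -0.11 ± 0.18 within FVF+ (adjusted p = 0.645) and by 0.08 ± 0.20 within FVF- (adjusted p = 0.850), and neither was called.

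**Figure D1:**
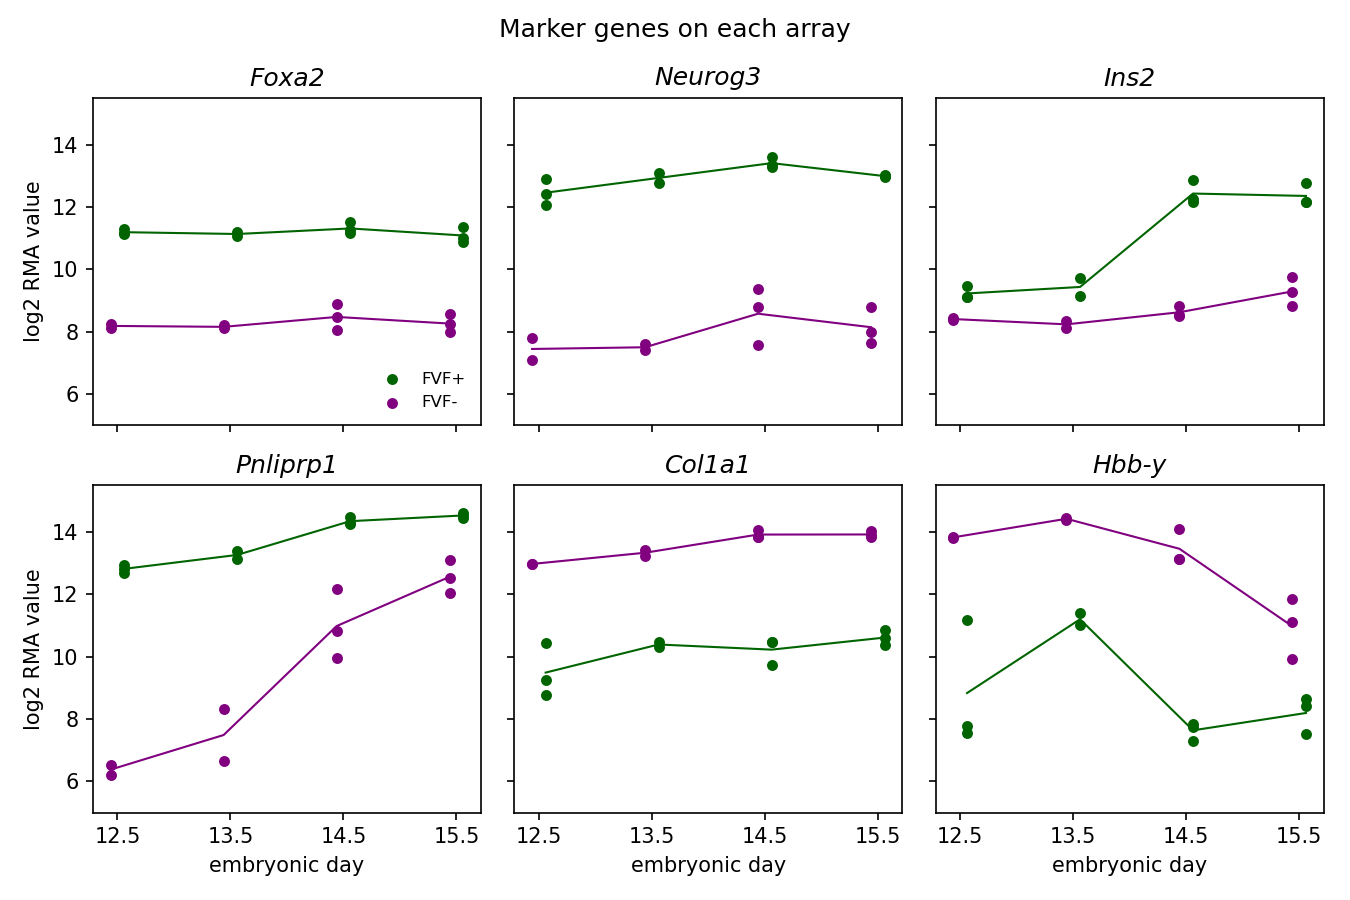
Log2 RMA value of 6 genes on each of the 21 arrays against embryonic day, with FVF+ in green and FVF- in purple; each point is 1 array and the lines join group means. Foxa2 lay at 10.87 or above on all FVF+ arrays and at 8.89 or below on all FVF- arrays, Pnliprp1 in FVF- went from a mean of 6.38 at E12.5 to 12.57 at E15.5, and Hbb-y lay at 11.01 to 11.40 on 3 FVF+ arrays of E12.5 and E13.5.

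What set Foxa2-Venus cells apart from the rest of the pancreas was asked first, as the mean of the 4 within-day differences. FVF+ cells carried the transcripts of pancreatic epithelium. Neurog3, the transcription factor that starts endocrine differentiation, was higher by 5.03 ± 0.19 log2 units (SE, adjusted p = 8.3e-14), and Neurod1, which acts downstream of it, by 4.95 ± 0.14 (adjusted p = 4.0e-15). Pdx1, a transcription factor needed for pancreas formation, was higher by 4.30 ± 0.14, and the adhesion genes Epcam and Cdh1 by 4.36 ± 0.18 and 4.28 ± 0.19. FVF- cells carried connective tissue, vascular and blood transcripts: Pdgfra, a growth factor receptor of mesenchyme, was lower in FVF+ by -3.88 ± 0.18 (adjusted p = 1.1e-12), and Cpa3, a protease of mast cells, by -4.55 ± 0.20 (adjusted p = 5.0e-13). In all, 10744 genes were called at an adjusted p under 0.05, 5886 higher and 4858 lower in FVF+, and 2284 of these differed at least 2-fold, 992 higher and 1292 lower. After cyclic loess normalization, 5457 were higher and 5395 lower.

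Among the gene lists fixed before the data were examined, all 16 measured pancreatic progenitor transcription factors were higher in FVF+, with a median of 3.21, led by Nkx2-2 (4.46 ± 0.19), Pdx1, Prox1 (3.99 ± 0.20) and Onecut1 (3.96 ± 0.29). Of 24 epithelial junction and keratin genes, 22 were higher and none lower. Esrp1, a splicing regulator of epithelia, and Cldn6, a tight junction claudin, led them with 4.71 ± 0.18 and 4.65 ± 0.20. The exceptions were Lgals4 (-0.12 ± 0.07) and the keratin Krt19 (0.04 ± 0.13), which were not called. Of 20 endocrine lineage genes, 18 were higher, including Rfx6 (4.80 ± 0.18), a transcription factor of islet cells. Runx1t1, a transcriptional corepressor, was lower (-1.16 ± 0.09). Of 26 hormone and secretory granule genes, 25 were higher, among them the amylin gene Iapp (4.50 ± 0.19), the granule protein gene Chgb (4.30 ± 0.19) and the peptide YY gene Pyy (3.95 ± 0.14). Of 28 acinar genes, 27 were higher, among them the lipase-related Pnliprp1 (4.39 ± 0.23) and Cel, the gene of bile salt-activated lipase (3.95 ± 0.18). Of 16 ductal genes, 12 were higher, such as Ambp (4.92 ± 0.28), Muc1 (4.56 ± 0.21) and Sox9 (3.44 ± 0.13), and 2 were lower, Anxa3 (-2.21 ± 0.12) and the carbonic anhydrase gene Car2 (-1.99 ± 0.12). The counts of these 6 lists were the same when adjusted over the list alone. Camera called each of the 6 lists at an adjusted p of 1.8e-04 or less. No such call held with an estimated correlation (adjusted p = 0.0559 with an estimated correlation for the first 5 lists and 0.0937 for the ductal list). Fry called each of the 6 lists (fry adjusted p of 1.2e-10 or less).

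Genes of the other pancreatic cell types were lower in FVF+. All 32 mesenchyme genes were lower, with a median of -2.98, including Lum, which encodes a matrix proteoglycan (-3.83 ± 0.18), and the transcription factors Tcf21 (-3.75 ± 0.13) and Prrx1 (-3.75 ± 0.16). All 12 smooth muscle genes were lower, led by desmin, Des (-3.89 ± 0.15), and smooth muscle actin, Acta2 (-2.92 ± 0.17). Of 8 mesothelium genes, 7 were lower, among them Wt1 (-3.15 ± 0.13), while Msln was not called (-0.07 ± 0.05). All 20 endothelium genes were lower, such as Cdh5, the cadherin of vascular endothelium (-2.85 ± 0.24), and Kdr, a receptor for vascular endothelial growth factor (-2.70 ± 0.17). All 22 macrophage and leukocyte genes were lower, such as Lyz2 (-3.67 ± 0.20) and Mrc1 (-3.34 ± 0.16). Of 14 red blood cell lineage genes, 12 were lower, led by the embryonic globin genes Hbb-y (-4.21 ± 0.36) and Hba-x (-3.66 ± 0.26), and Epb42 was higher (1.35 ± 0.14). Of 17 neural crest, glia and neuron genes, 12 were lower, such as Stmn2 (-3.51 ± 0.11), and 4 were higher, including the receptor genes Erbb3 (2.32 ± 0.09) and Ret (1.09 ± 0.08). When adjusted over the list alone, 13 red blood cell lineage genes were lower and the other counts were the same. Camera called all 7 lists, with adjusted p between 1.2e-20 and 0.00317. None was called with an estimated correlation (adjusted p = 0.0559 with an estimated correlation for mesenchyme, smooth muscle, mesothelium, red blood cell and macrophage genes, 0.109 for endothelium and 0.101 for neural crest). Fry called all 7 lists (fry adjusted p of 6.2e-09 or less).

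Signalling and housekeeping lists went both ways. Of 20 Notch pathway genes, 7 were higher in FVF+, including the ligand gene Dll1 (2.04 ± 0.09), and 8 lower, including Hey2 (-3.16 ± 0.12) and the receptor gene Notch3 (-1.12 ± 0.08). Of 25 Wnt and planar cell polarity genes, 9 were higher, such as Wnt7b (2.00 ± 0.10) and Celsr2 (1.67 ± 0.08), and 14 lower, such as Wnt5a (-3.27 ± 0.15) and the secreted Wnt inhibitor gene Sfrp2 (-3.13 ± 0.12). Of 20 basement membrane and integrin genes, 4 were higher, including the epithelial integrin genes Itga6 (1.60 ± 0.10) and Itgb4 (1.38 ± 0.09), and 16 lower, led by the nidogen gene Nid1 (-3.87 ± 0.19). Of 29 cell cycle genes, 16 were higher, among them Cenpf (0.69 ± 0.15), and 2 lower. Of 18 genes of neighbouring organs, 8 were higher, including alpha-fetoprotein, Afp (2.79 ± 0.11), and albumin, Alb (1.99 ± 0.23), and 2 lower, including Tlx1, a transcription factor of the spleen (-3.05 ± 0.13). Of 18 immediate early and heat shock genes, 3 were higher and 5 lower, led by Dusp1 (-1.55 ± 0.22). Adjusted over the list alone, 17 cell cycle genes were higher and the other counts were the same. Camera called the Wnt (adjusted p = 0.0302), basement membrane (2.3e-04) and cell cycle (0.0392) lists. These calls were lost with an estimated correlation (adjusted p = 0.192, 0.171 and 0.536 with an estimated correlation). The Notch, neighbouring organ and immediate early lists were not called by camera (adjusted p = 0.313, 0.118 and 0.313). Fry called the Wnt (fry adjusted p = 2.0e-09), basement membrane (1.3e-08), cell cycle (0.00617), Notch (2.5e-04) and neighbouring organ lists (2.4e-05). It did not call the immediate early list (0.273).

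The largest differences of all 19296 genes included genes of no list. Serpina1c, an alpha-1 antitrypsin gene, was higher in FVF+ by 5.59 ± 0.27, and Ugt2b34, a glucuronosyltransferase gene, by 5.20 ± 0.21. Cpn1, the carboxypeptidase N gene (4.94 ± 0.24), Cltrn (4.91 ± 0.16) and Akr1c19 (4.84 ± 0.16) followed. The largest differences in the other direction, after Cpa3 and Hbb-y, were those of Lrrc17 (-3.99 ± 0.14), the lysyl oxidase gene Lox (-3.93 ± 0.17), the protocadherin gene Pcdh18 (-3.91 ± 0.20) and the collagen receptor gene Ddr2 (-3.90 ± 0.15).

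**Figure D2:**
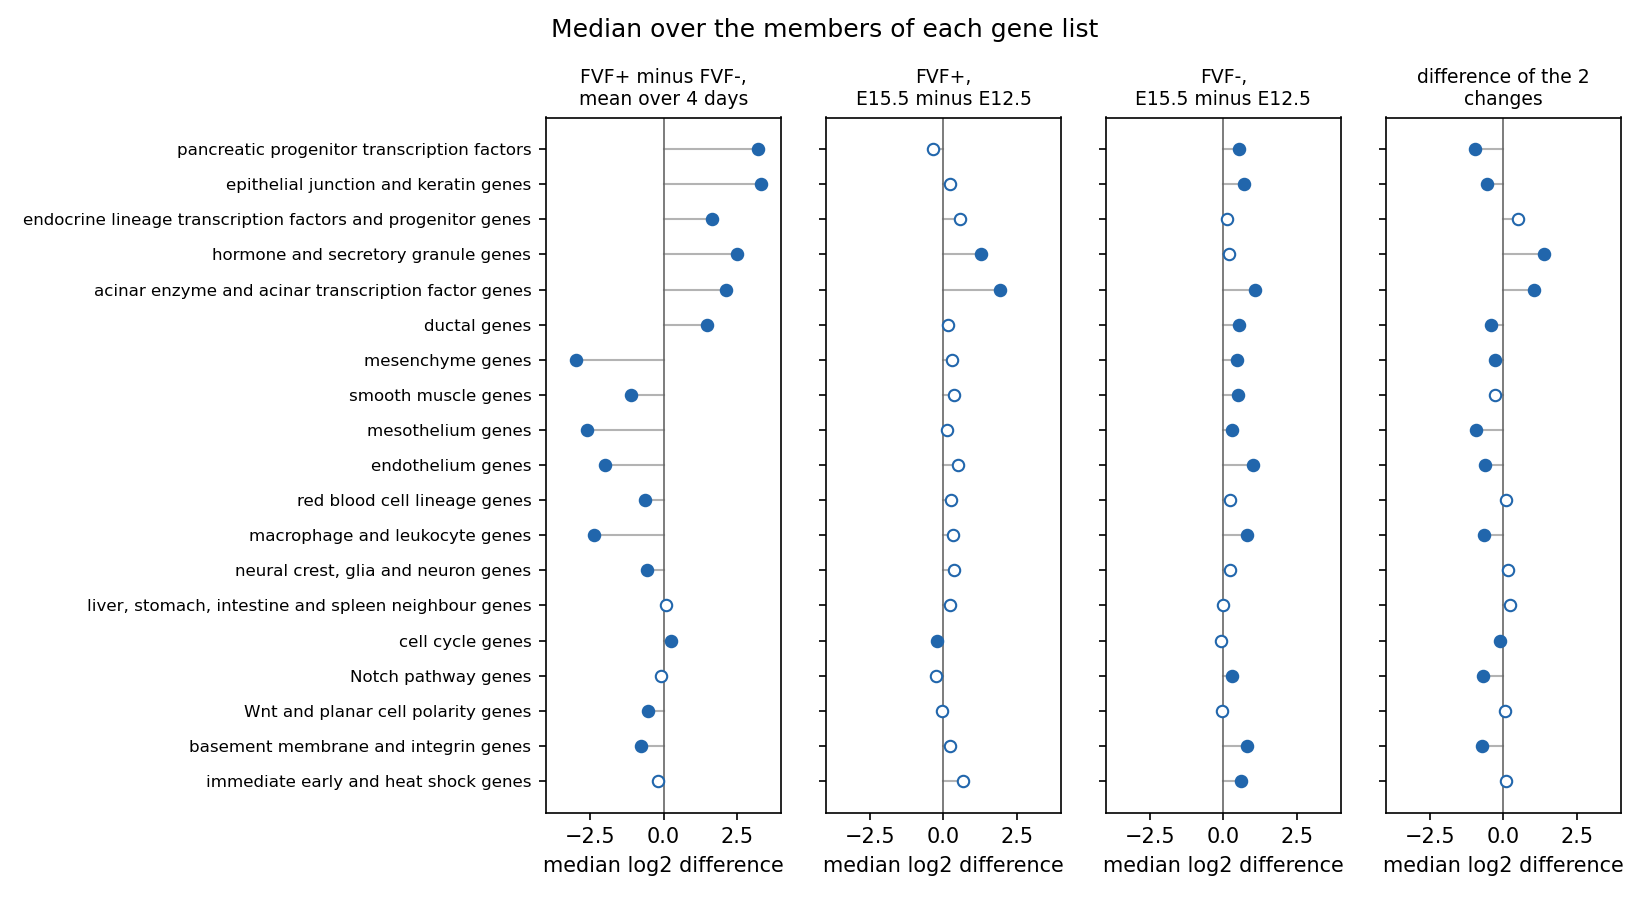
Median log2 difference over the measured members of 19 gene lists in 4 comparisons; filled points were called by camera with its preset correlation at an adjusted p under 0.05, and open points were not. Progenitor and epithelial genes had medians of 3.21 and 3.30 in FVF+ against FVF-, mesenchyme genes -2.98, and acinar genes rose in FVF+ with a median of 1.91 between E12.5 and E15.5.

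Within single days, the sorts differed in 6930 genes at E12.5, 5970 at E13.5, 8604 at E14.5 and 8478 at E15.5. At E12.5, Serpina1c was higher in FVF+ by 7.25 ± 0.56 and Serpina6, the gene of corticosteroid-binding globulin, by 6.56 ± 0.48, while Tcf21 was lower by -4.33 ± 0.27 and Osr1 by -4.31 ± 0.45. At E13.5, Naaladl2 (6.01 ± 1.09) and Pnliprp1 (5.78 ± 0.52) were higher, and Cpa3 (-5.01 ± 0.45) and the steroid dehydrogenase gene Hsd3b6 (-4.46 ± 0.55) lower. At E14.5, Neurod1 (5.89 ± 0.26), Iapp (5.78 ± 0.35) and Cltrn (5.51 ± 0.30) were higher, and Hbb-y (-5.83 ± 0.67) and Lrrc17 (-4.59 ± 0.26) lower. At E15.5, Scgn, which encodes a calcium-binding protein of islet cells (5.25 ± 0.31), and Iapp (5.16 ± 0.35) were higher, and the matrix genes Ogn (-5.19 ± 0.29) and Aspn (-5.12 ± 0.26) lower. Higher in FVF+ on all 4 days were 1780 genes, against 29.6 expected of independent lists, and lower on all 4 days were 2041, against 23.0. Another 390 genes were called in opposite directions on different days. Camera with an estimated correlation called the progenitor, mesenchyme and macrophage lists at E13.5 (adjusted p = 0.0422 for each), 7 lists at E14.5 (the progenitor, endocrine lineage, hormone, acinar, mesenchyme, red blood cell and macrophage lists, adjusted p = 0.0380 for each) and none at E12.5 or E15.5 (lowest adjusted p = 0.0552 and 0.0566). The neighbouring organ list at E12.5 had a median of -0.06 and a mean of 0.29, and the Notch list at E13.5 a median of 0.08 with a test directed downward. Hbb-y in FVF+ had means of 11.21 ± 0.28 at E13.5 (SD, n = 2) and 7.64 ± 0.29 at E14.5 (n = 3), a fall called in the step between these days.

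Whether FVF+ cells changed over time was asked with E15.5 against E12.5. In both sorts the numbered array codes rose with embryonic day, from 02 to 06 at E12.5 up to 15 to 20 at E15.5. What the codes mean is not given. If they follow the order of processing, changes with day cannot be told apart from changes with that order. Acinar enzyme genes and hormone genes rose most. Cpb1, the carboxypeptidase B gene, rose by 5.99 ± 0.32 (SE, adjusted p = 9.0e-10), from a mean of 6.37 ± 0.07 to 12.36 ± 0.04 (SD, n = 3 each). Sst, the somatostatin gene, rose by 4.84 ± 0.24 (adjusted p = 5.3e-10), and the insulin gene Ins2 by 3.13 ± 0.23 (adjusted p = 2.8e-08). Sox11, a transcription factor of embryonic tissues, fell by 2.90 ± 0.25 (adjusted p = 1.6e-07). In all, 9048 genes were called, 5317 that rose and 3731 that fell, and 1040 changed at least 2-fold, 411 up and 629 down.

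Of 28 acinar genes, 24 rose in FVF+ and none fell, with a median of 1.91. Rnase1 (5.38 ± 0.36), the elastase genes Cela3b (4.90 ± 0.29) and Cela2a (4.45 ± 0.25) and the trypsinogen gene Prss3 (4.49 ± 0.19) rose with Cpb1. Rbpjl, an acinar transcription factor gene, changed by 1.13 ± 0.52 and was not called, nor was the colipase gene Clps (0.46 ± 0.28), whose FVF+ mean was already 14.40 ± 0.09 at E12.5 (SD, n = 3). Of 26 hormone and secretory granule genes, 23 rose, with a median of 1.28, including the zinc transporter gene Slc30a8 (3.36 ± 0.17) and Scgn (3.12 ± 0.31). Slc2a2, the GLUT2 glucose transporter gene, fell by 1.70 ± 0.23. The glucagon gene Gcg stood at -0.07 ± 0.57 and was not called, with an FVF+ mean of 14.19 ± 0.23 at E12.5 and 14.13 ± 0.01 at E15.5 (SD, n = 3 each). Of 20 endocrine lineage genes, 9 rose, such as Myt1 (1.69 ± 0.24), Mafa (1.27 ± 0.16) and Pax6 (1.25 ± 0.32), and 2 fell, Sox4 (-0.97 ± 0.18) and Dll1 (-0.50 ± 0.17). The counts of these 3 lists were the same when adjusted over the list alone. Camera called the acinar (adjusted p = 2.9e-13) and hormone (1.2e-09) lists and not the endocrine lineage list (0.0964). Both calls were lost with an estimated correlation (adjusted p = 0.311 and 0.498 with an estimated correlation).

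Progenitor and proliferation genes were among those that fell in FVF+. Of 16 progenitor transcription factors, 7 fell, including Onecut1 (-1.35 ± 0.54), Prox1 (-1.17 ± 0.37), Sox9 (-1.04 ± 0.24) and Nkx6-1 (-0.73 ± 0.26), and 2 rose, Ptf1a (0.87 ± 0.29) and Gata4 (0.70 ± 0.15). Of 29 cell cycle genes, 12 fell, including the mitotic genes Bub1 (-1.59 ± 0.26), Cenpe (-1.49 ± 0.37) and Kif11 (-1.17 ± 0.24), and only Birc5 rose (0.50 ± 0.19). Onecut1 was not called after quantile normalization, nor Onecut1 and Nkx6-1 after cyclic loess normalization. The proliferation marker Mki67 stood at -0.24 ± 0.21 and was not called. Of 20 Notch pathway genes, 9 fell, led by the target gene Hey1 (-1.91 ± 0.17), Notch3 (-1.30 ± 0.14) and the ligand gene Jag1 (-1.03 ± 0.12), and 6 rose, led by Lfng (0.94 ± 0.12). Of 25 Wnt and planar cell polarity genes, 8 fell, including the receptor gene Fzd2 (-1.62 ± 0.11) and the polarity gene Vangl2 (-1.02 ± 0.15), and 4 rose. Adjusted over the list alone, 3 progenitor transcription factors rose and the other counts were the same. Camera called the cell cycle list (adjusted p = 0.00178), a call lost with an estimated correlation (adjusted p = 0.809 with an estimated correlation). The progenitor, Notch and Wnt lists were not called (adjusted p = 0.146, 0.0964 and 0.0964).

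The remaining lists were not called in FVF+ between E12.5 and E15.5 (camera adjusted p from 0.0964 to 0.839). Of 24 epithelial genes, 8 rose, led by Krt19 (1.03 ± 0.24), and none fell, and of 16 ductal genes 4 rose, led by Clu (1.85 ± 0.19), and 4 fell. Of 32 mesenchyme genes, 11 rose, such as Lum (1.84 ± 0.32) and the collagen gene Col1a1 (1.12 ± 0.29), and 4 fell, such as the fibronectin gene Fn1 (-1.11 ± 0.14). Members of the smooth muscle (4 of 12), endothelium (5 of 20), macrophage (6 of 22) and red blood cell (4 of 14) lists rose and none fell, with C1qa, a complement gene of macrophages, the largest of them (1.59 ± 0.25). Col1a1 lay at 10.45, 9.27 and 8.76 on FVF+ E12.5 replicates 1, 2 and 3 and at 10.39 to 10.86 at E15.5. That replicate 1 also had a higher Hbb-y signal, 11.18 against 7.79 and 7.54. Whether FVF- cells in the FVF+ samples contributed to these values was not tested. Of 17 neural crest genes, 6 rose, led by Ret (1.55 ± 0.15), and 1 fell, and of 18 immediate early genes, 7 rose, including Atf3 (1.68 ± 0.51) and Fos (1.59 ± 0.61). Without E15.5 replicate 3, Atf3 changed by 0.66 and Fos by 0.86, and Fos was not called then or after either of these normalizations. Genes of neighbouring organs included 8 that rose, led by Vil1 (1.29 ± 0.17), and 3 that fell, led by the fibrinogen gene Fgg (-2.29 ± 0.13). Of 8 mesothelium genes 1 rose and 2 fell, and the list had a median of 0.12 and a mean of -0.10. Of 20 basement membrane genes 7 rose and 5 fell, with a median of 0.23 and a test directed downward. Adjusted over the list alone, 13 mesenchyme and 5 macrophage genes rose, 6 basement membrane genes fell, and the other counts were the same.

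The largest rises in FVF+ also held Pdia2, a pancreatic protein disulfide isomerase gene (5.38 ± 0.34), and the trypsinogen gene Try10 (5.19 ± 0.35). The largest falls included Kynu, the kynureninase gene (-2.86 ± 0.17), Serpina1c (-2.85 ± 0.50), Rimklb (-2.77 ± 0.20) and Mir181b-2 (-2.73 ± 0.30). Stxbp4 (-3.09 ± 0.37), Zfp985 (-2.86 ± 0.38) and Zfp141 (-2.69 ± 0.45) also fell, and the second probe set of each gene changed less, by -1.34, -0.39 and -0.46. With only genes tested whose mean in some group was above 8.77, the median of all values, 5945 genes were called between E12.5 and E15.5 in FVF+, 2648 that rose and 3297 that fell. Rises made up 58.8% of all 9048 calls, 51.7% after quantile normalization and 51.6% after cyclic loess normalization. Of the 9048 genes, 6485 were still called after quantile normalization and 6355 after cyclic loess normalization.

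FVF- cells changed over the same days in acinar, matrix, vascular and blood genes. Pnliprp1 rose by 6.19 ± 0.48 (SE, adjusted p = 2.3e-07), from 6.38 ± 0.23 (SD, n = 2) to 12.57 ± 0.54 (n = 3), and Ctrb1, the chymotrypsinogen gene, by 5.42 ± 0.44 (adjusted p = 3.3e-07). Agtr2, the type 2 angiotensin receptor gene, rose by 4.83 ± 0.38, and the matrix genes Aspn and Lum by 3.99 ± 0.29 and 3.63 ± 0.36. Hbb-y and Hbb-bh1, embryonic globin genes, fell by 2.86 ± 0.75 and 2.39 ± 0.26, and Alas2, which encodes the first enzyme of haem synthesis in red cells, rose by 2.21 ± 0.17. In all, 3945 genes were called, 2073 that rose and 1872 that fell, and 641 changed at least 2-fold, 488 up and 153 down.

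Of 28 acinar genes, 15 rose in FVF- and none fell, with a median of 1.09, including Clps (3.99 ± 0.31) and Cel (2.94 ± 0.38). Of 26 hormone genes, 4 rose, among them Cpe (2.20 ± 0.27) and Ins2 (0.89 ± 0.26), and Gcg was not called (-1.51 ± 0.63). Of 24 epithelial genes, 12 rose, led by Krt19 (2.29 ± 0.27) and Cdh1 (1.70 ± 0.38), and Prom1 fell (-0.80 ± 0.15). Of 16 progenitor transcription factors, 4 rose, including Glis3 (1.03 ± 0.12) and Gata6 (0.77 ± 0.10), and of 16 ductal genes 9 rose. Of 32 mesenchyme genes, 16 rose, such as the periostin gene Postn (2.19 ± 0.34) and Col6a2 (2.04 ± 0.19), and 2 fell, Hand2 (-0.82 ± 0.28) and Twist1 (-0.39 ± 0.11), of which Hand2 was not called after cyclic loess normalization. Of 20 basement membrane genes, 11 rose, such as the laminin gene Lama4 (2.23 ± 0.29) and the collagen gene Col4a2 (1.59 ± 0.19), and Lama1 fell (-1.71 ± 0.14). Of 20 endothelium genes, 15 rose, led by Plvap (1.57 ± 0.34). Of 22 macrophage and leukocyte genes, 14 rose, including Lyz2 (2.18 ± 0.42) and Coro1a (1.94 ± 0.22). Of 20 Notch genes, 9 rose, including Nrarp (1.47 ± 0.20). Of 12 smooth muscle genes 6 rose and 1 fell, of 8 mesothelium genes 4, and of 18 immediate early and heat shock genes 2, Hspb1 (1.68 ± 0.23, and 1.27 on its second probe set) and Junb (0.85 ± 0.19), while 1 fell. Adjusted over the list alone, the risers were 20 acinar, 4 hormone, 14 epithelial, 5 progenitor, 9 ductal, 17 mesenchyme, 14 basement membrane, 17 endothelium, 17 macrophage, 9 Notch, 8 smooth muscle, 4 mesothelium and 2 immediate early genes, and 3 mesenchyme genes and 1 each of the epithelial, smooth muscle, basement membrane and immediate early lists fell.

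Camera called these lists as raised in FVF-, with adjusted p from 1.1e-11 for acinar genes to 0.0306 for immediate early genes, except the hormone list (0.135). No call held with an estimated correlation (adjusted p = 0.144 with an estimated correlation for acinar, ductal, macrophage, Notch and basement membrane genes, 0.352 for progenitor, epithelial, mesenchyme, smooth muscle and endothelium genes, 0.409 for mesothelium and 0.528 for immediate early genes). The red blood cell list (5 rose, 3 fell), endocrine lineage list (3 rose, 3 fell), neural crest list (3 rose, 4 fell), Wnt list (3 rose, 5 fell), cell cycle list (1 rose, 2 fell) and neighbouring organ list (1 rose, none fell) were not called, with adjusted p of 0.126, 0.326, 0.321, 0.472, 0.323 and 0.827. Counts of these 6 lists adjusted over the list alone were 6 and 3, 3 and 3, 4 and 4, 3 and 7, 1 and 1, and 0 and 0. The red blood cell list had a median of 0.24 and a mean of -0.14, with a test directed upward. Among the largest falls were Hsd3b6 (-2.88 ± 0.50), the chromatin protein gene Hmga2 (-2.72 ± 0.29), the growth factor receptor gene Fgfr2 (-2.42 ± 0.28) and the neurokinin gene Tac2 (-2.41 ± 0.33), and Lef1, a mediator of Wnt signalling, fell by 1.69 ± 0.16. Of the calls, 52.6% were rises, a share that was 36.8% with each array centred on its median, 47.4% after quantile normalization, 48.3% with dim genes left out and 64.3% after cyclic loess normalization. Without E12.5 replicate 1 or 2 of FVF-, 1995 and 2043 genes were called.

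**Figure D3:**
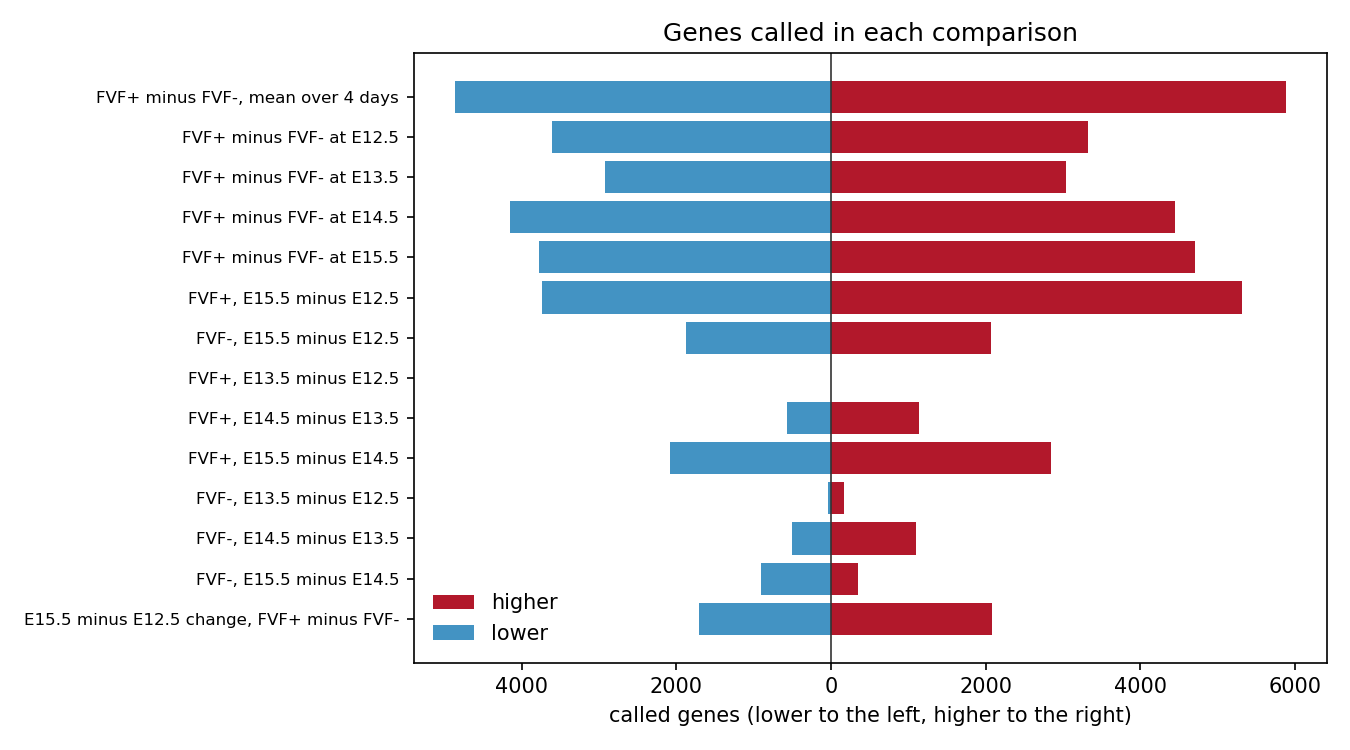
Number of genes called at an adjusted p under 0.05 in each of 14 comparisons, with genes that were higher or rose to the right of 0 and genes that were lower or fell to the left. The 4 within-day comparisons of the sorts called 5970 to 8604 genes, and the step from E12.5 to E13.5 in FVF+ called 1.

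Day-to-day steps within FVF+ differed in size. From E12.5 to E13.5, 1 gene was called by limma, Abca8b, a lipid transporter gene, which fell by 0.70 ± 0.10 (adjusted p = 0.0228), while 1873 genes had an unadjusted p under 0.05. From E13.5 to E14.5, 1707 genes were called, 1134 up and 573 down. Try10 rose by 4.37 ± 0.39, Prss3 by 3.38 ± 0.21 and Sst by 3.29 ± 0.27, while Hbb-y fell by 3.56 ± 0.75, Tgfbi by 1.98 ± 0.42 and the platelet gene Ppbp by 1.91 ± 0.28. Of 26 hormone genes, 22 rose in this step and 1 fell (23 and 1 adjusted over the list alone; camera adjusted p = 6.2e-26), and of 28 acinar genes, 15 (21 adjusted over the list alone; 6.9e-16). Both list calls were lost with an estimated correlation (adjusted p = 0.0630 and 0.0989 with an estimated correlation). From E14.5 to E15.5, 4931 genes were called, 2844 up and 2087 down, of which 170 changed at least 2-fold, 34 up and 136 down. Rnase1 rose by 2.70 ± 0.36, Vaultrc5 by 2.41 ± 0.49 and Pdia2 by 2.31 ± 0.34, while Ly96 fell by 2.81 ± 0.46. Stxbp4 (-2.61 ± 0.37) and Scoc (-2.37 ± 0.38) fell too, on the brighter of their probe sets. Of 28 acinar genes, 14 rose (14 adjusted over the list alone; camera adjusted p = 6.7e-05), a call lost with an estimated correlation (adjusted p = 0.956 with an estimated correlation), and of 26 hormone genes 3 did. The first step called 128 genes without E12.5 replicate 1, whose Hbb-y signal was 11.18, against 7.79 and 7.54 on the other arrays of that group. The second step called 127 genes with a term for the 3 E13.5 arrays that carry letter codes. That term rests on the FVF- arrays, since both FVF+ arrays of E13.5 carry such codes, and it raised the median SE of the 1619 calls that ended from 0.14 to 0.24 while their median absolute change went from 0.60 to 0.44. With it, Hbb-y (-3.62 ± 1.42), Tgfbi (-1.62 ± 0.79) and Ppbp (-1.18 ± 0.49) were not called, and the fall of Hbb-y was about as large with a wider error. The third step called 2721 genes after cyclic loess normalization, 1224 up and 1497 down, and 2491 with dim genes left out, 738 up and 1753 down. Without E14.5 replicate 3 it called 2222, 1117 up and 1105 down, and without E14.5 replicate 2 it called 5687, 3075 up and 2612 down.

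Other lists moved in the FVF+ steps as well. From E12.5 to E13.5, camera called 8 lists as raised although limma called none of their members: mesenchyme (median 0.50, adjusted p = 3.8e-11), endothelium (0.51, 4.4e-08), neural crest (0.33, 7.6e-06), smooth muscle (0.28, 1.5e-04), mesothelium (0.46, 0.00110), red blood cell (0.22, 0.00973), acinar (0.24, 0.00993) and macrophage genes (0.24, 0.0138). Adjusted over the list alone, 12 mesenchyme, 4 mesothelium, 3 neural crest and 2 endothelium genes rose and none of the other 4 lists. These calls were lost with an estimated correlation (adjusted p = 0.124 with an estimated correlation for neural crest, 0.334 for mesenchyme, smooth muscle, mesothelium and red blood cell, 0.412 for endothelium, and 0.740 for acinar and macrophage genes). All of these lists but the acinar one were lower in FVF+ than in FVF-. Hbb-y and Col1a1 lay at 11.40 and 10.33 on FVF+ E13.5 replicate 1 and at 11.01 and 10.46 on replicate 2. On FVF+ E12.5 replicates 1, 2 and 3, Hbb-y lay at 11.18, 7.79 and 7.54 and Col1a1 at 10.45, 9.27 and 8.76. Whether FVF- cells in the FVF+ samples contributed to these list changes was not tested. From E13.5 to E14.5, camera called mesenchyme (median -0.30, adjusted p = 6.8e-04), mesothelium (-0.49, 0.0409) and neighbouring organ genes (-0.23, 0.0149) as lowered and endocrine lineage (0.65, 5.6e-07) and epithelial genes (0.25, 0.00868) as raised. In the lowered lists 5 of 32, 1 of 8 and 2 of 18 members fell (7, 2 and 5 adjusted over the list alone), with 1 neighbouring organ gene that rose, and in the raised lists 8 of 20 and 1 of 24 rose (10, with 1 that fell, and 1 adjusted over the list alone). No such call held with an estimated correlation (adjusted p = 0.583, 0.583, 0.567, 0.191 and 0.740 with an estimated correlation). From E14.5 to E15.5, cell cycle (median -0.22, adjusted p = 0.00334) and endocrine lineage genes (-0.32, 0.0132) were called as lowered, with 5 and 2 members that fell (5 and 1 adjusted over the list alone), and neighbouring organ genes as raised (0.22, 0.0214), with 4 that rose (4 adjusted over the list alone). All 3 calls were lost with an estimated correlation (adjusted p = 0.956 with an estimated correlation for each).

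In FVF-, 197 genes changed from E12.5 to E13.5, 166 of them upward. Ngp, a neutrophil granule gene, rose by 2.90 ± 0.30, Aspn by 2.75 ± 0.32 and Lum by 2.58 ± 0.40, while Snord53 fell by 1.13 ± 0.23 and the relaxin receptor gene Rxfp1 by 0.95 ± 0.10. Of 22 macrophage and leukocyte genes, 5 rose (14, with 1 that fell, adjusted over the list alone; camera adjusted p = 2.4e-15), a call lost with an estimated correlation (adjusted p = 0.143 with an estimated correlation). From E13.5 to E14.5, 1602 genes were called, 1096 up and 506 down, led by Pnliprp1 (3.50 ± 0.48), Ctrb1 (3.13 ± 0.44) and Serpina6 (2.72 ± 0.48), and by falls of Hsd3b6 (-2.71 ± 0.50) and Hbb-bh1 (-2.04 ± 0.26). From E14.5 to E15.5, 1253 genes were called, 355 up and 898 down (38 and 13 at least 2-fold), led by Try10 (2.49 ± 0.35), Rnase1 (1.84 ± 0.36) and Cela3b (1.75 ± 0.29), and by falls of Hbb-y (-2.49 ± 0.67), Hsd3b6 (-1.81 ± 0.45; -1.15 and not called without E14.5 replicate 3) and Hba-x (-1.68 ± 0.48). In that last step, 12 of 28 acinar genes rose (16 adjusted over the list alone; camera adjusted p = 2.4e-11), a call lost with an estimated correlation (adjusted p = 0.232 with an estimated correlation). With a term for letter-coded arrays the middle step called 33 genes, the 1574 calls that ended having a median absolute change of 0.58 with a median SE of 0.14 before and 0.46 with 0.17 after. At E13.5, FVF- replicate 2 carried a letter code and replicate 1 did not. In the FVF- steps this term thus amounts to leaving out that replicate 2, and is no separate check. With this term Pnliprp1 changed in the middle step by 2.66, Ctrb1 by 2.16, Serpina6 by 2.30, Hsd3b6 by -2.42 and Hbb-bh1 by -2.08. Fitted on the arrays of each step alone the 3 steps called 1, 0 and 1. Rises made up 68.4% of the calls of the middle step, against 55.1% with each array centred on its median and 57.0% after quantile normalization, and 28.3% of those of the last step, against 41.3% after cyclic loess normalization, in which Hbb-y and Hba-x were not called.

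More lists were called by camera in the FVF- steps. From E12.5 to E13.5 these were endothelium, basement membrane, mesenchyme, ductal, progenitor, mesothelium and Notch genes as raised (adjusted p from 1.3e-06 to 0.0169) and neighbouring organ genes as lowered (0.0385). By limma 3 mesenchyme, 2 progenitor, 1 ductal and 1 mesothelium genes rose, and adjusted over the list alone 7 (with 1 that fell), 2, 1 and 2, with 5 basement membrane genes and none of the other lists. From E13.5 to E14.5, camera called epithelial, acinar, progenitor, smooth muscle, ductal, hormone and neural crest genes as raised (adjusted p from 1.5e-04 to 0.0478), with 5, 6, 4, 2, 3, 1 and 5 members that rose (11, with 1 that fell, and 6, 4, 6, 6, 1 and 6 adjusted over the list alone). The E14.5 arrays were spread on the epithelial and progenitor lists, with median deviations from the group mean of -0.58 and -0.50 on replicate 2 and of 0.55 and 0.52 on replicate 3, and Epcam at 8.15, 7.16 and 9.31 on replicates 1, 2 and 3. From E14.5 to E15.5, endothelium genes were called as raised (adjusted p = 7.8e-06), with 2 that rose (6 adjusted over the list alone), and Wnt genes as lowered (1.0e-04), with 4 that fell (6 adjusted over the list alone). None of these calls held with an estimated correlation (adjusted p from 0.376 to 0.471 with an estimated correlation in the first step, from 0.618 to 0.639 in the middle step, and 0.827 and 0.232 in the last).

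Whether the change from E12.5 to E15.5 differed between the sorts was tested as an interaction. Sst rose in FVF+ by 4.60 ± 0.36 more log2 units than in FVF- (SE, adjusted p = 5.2e-07), Slc30a8 by 3.30 ± 0.25 more (adjusted p = 4.7e-07) and Prss3 by 3.80 ± 0.28 more (adjusted p = 4.1e-07). Agtr2 rose more in FVF- (-3.90 ± 0.50). Pnliprp1 (-4.47 ± 0.64) and Ctrb1 (-4.20 ± 0.59) had the higher measured change in FVF-, where they started lower. Their FVF+ means, 12.82 ± 0.13 and 13.70 ± 0.33 at E12.5 (SD, n = 3 each), were 14.54 ± 0.10 and 14.92 ± 0.06 at E15.5 (n = 3 each), close to the highest value of the table, 15.31, which limits the rise that the array can measure. The matrix genes Aspn (-3.77 ± 0.39), Adamts5 (-3.77 ± 0.36) and Ogn (-3.71 ± 0.43) also had the higher change in FVF-. In all, 3786 genes were called, 2083 with the higher change in FVF+ and 1703 with the higher change in FVF-, and 1101 differed at least 2-fold, 339 and 762. Of the genes that rose in FVF+, 932 also rose in FVF-, against 571.2 expected of independent lists, and 1004 fell in both, against 362. Another 111 rose in FVF+ and fell in FVF-, and 176 fell in FVF+ and rose in FVF-.

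By list, 15 of 26 hormone genes had the higher change in FVF+, including Scgn (2.85 ± 0.47) and the ghrelin gene Ghrl (2.69 ± 0.34), and Slc2a2 the lower (-1.86 ± 0.34). Of 28 acinar genes, 15 had the higher change in FVF+, such as Cpb1 (3.50 ± 0.48) and Rnase1 (3.45 ± 0.55), and 4 the lower, Pnliprp1, Ctrb1, Clps (-3.53 ± 0.42) and Cpa1 (-1.66 ± 0.35). The limit on measured rises applies to all 4, with FVF+ means of Clps and Cpa1 of 14.40 ± 0.09 and 14.75 ± 0.06 at E12.5 and of 14.87 ± 0.09 and 14.89 ± 0.04 at E15.5 (SD, n = 3 each). Among 20 Notch pathway genes, 12 had the lower change in FVF+, including Hey1 (-2.56 ± 0.25), Nrarp (-2.40 ± 0.27), Notch3 (-1.44 ± 0.21) and Notch1 (-1.35 ± 0.18), and Rfng the higher (0.44 ± 0.15). Lower changes in FVF+ were also called for 5 of 16 progenitor transcription factors, such as Pdx1 (-1.31 ± 0.39), for 10 of 20 basement membrane genes, such as Hspg2 (-1.43 ± 0.24), for 11 of 32 mesenchyme genes, such as Fn1 (-2.28 ± 0.21), for 5 of 22 macrophage genes, such as Coro1a (-1.58 ± 0.29), and for 5 of 29 cell cycle genes, such as Bub1 (-1.38 ± 0.39). Higher changes were called for 2 basement membrane genes, 1 mesenchyme gene and none of the other 3 lists. Adjusted over the list alone, these counts were 15 hormone genes up and 2 down, 17 acinar up and 4 down, 2 Notch up and 12 down, 2 basement membrane up and 10 down, 3 mesenchyme up and 12 down, and 6 progenitor, 5 macrophage and 5 cell cycle genes down. A lower change in FVF+ can come from a fall in FVF+, a rise in FVF- or both. Among the progenitor transcription factors called, Sox9 and Nkx6-1 fell in FVF+, whereas Glis3 and Gata6 rose in FVF-. Whether FVF+ cells in the FVF- samples contributed to these differences was not tested. Camera called 12 lists, the hormone list at 1.2e-07 and the Notch list at 1.1e-05, and none with an estimated correlation (adjusted p = 0.395 and 0.0819 with an estimated correlation, and 0.395 or more for the other 10 lists). Ret (2.26 ± 0.23) and Lef1 (1.79 ± 0.22) had the higher change in FVF+, and the fibrinogen gene Fgg the lower (-2.31 ± 0.20). Rises over FVF- made up 55.0% of the 3786 calls, 40.3% of those after cyclic loess normalization, 43.7% of those with dim genes left out and 46.6% of those with a fixed block of day and replicate number. The share was 64.9% with each array centred on its median and 57.4% with array weights. Without FVF- E12.5 replicate 2, 1818 genes were called. The red blood cell list had a median of 0.09 with a test directed downward, the neighbouring organ list a median of 0.22 and a mean of -0.01, and the Wnt list a median of 0.07 and a mean of -0.15, and none of these 3 lists was called.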

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

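The tests of acinar genes in FVF-, of level dependence and of the E14.5 arrays were chosen after the results were seen, and the counts over other splits of the arrays before.

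The change from E12.5 to E15.5 differed between FVF+ and FVF- for 3786 genes by the interaction test, which is what singled out the results in this and the next paragraph. Each difference in both is the FVF+ change minus the FVF- change in log2 units. By list, the medians were 1.39 for hormone genes, 1.05 for acinar genes, -0.95 for progenitor transcription factors, -0.94 for mesothelium, -0.71 for basement membrane, -0.68 for Notch, -0.64 for macrophages, -0.62 for endothelium, -0.55 for epithelial genes, -0.41 for ductal genes, -0.27 for mesenchyme and -0.10 for cell cycle genes. The list calls rested on the preset correlation of camera, and none held with an estimated correlation.

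Among hormone and endocrine genes, the differences were 4.60 for Sst, 3.30 for Slc30a8, 2.85 for Scgn, 2.69 for Ghrl, 2.24 for Ins2, 1.51 for Myt1, 0.93 for Mafa, -0.86 for Dll1 and -1.86 for Slc2a2. Among acinar genes they were 3.80 for Prss3, 3.50 for Cpb1, 3.45 for Rnase1, 3.04 for Cela3b, 2.85 for Cela2a, 3.97 for Pdia2, and -1.66 for Cpa1, -3.53 for Clps, -4.20 for Ctrb1 and -4.47 for Pnliprp1. The FVF+ means of these last 4 genes were already 12.82 to 14.75 at E12.5 and were 14.54 to 14.92 at E15.5, under a highest value of 15.31 in the whole table, which limits the rise the array can measure in FVF+. Progenitor, epithelial and ductal genes had -1.45 for Glis3, -1.31 for Pdx1, -1.30 for Nkx6-1, -1.24 for Gata6, -1.05 for Sox9, -1.69 for Cdh1, -1.26 for Krt19 and 1.10 for Prom1. Mesenchyme and matrix genes had -3.77 for Adamts5, -3.77 for Aspn, -3.71 for Ogn, -2.28 for Fn1, -1.79 for Lum, -1.45 for Postn, -1.43 for Hspg2, -1.32 for Lama4, -1.24 for Col4a2, -1.03 for Col6a2, 0.61 for Twist1 and 0.69 for Lama1. Signalling and cell cycle genes had -2.56 for Hey1, -2.40 for Nrarp, -1.44 for Notch3, -1.35 for Notch1, -1.06 for Jag1, 0.44 for Rfng, -1.49 for Fzd2, 1.79 for Lef1, 1.61 for Fgfr2, 2.26 for Ret, 1.83 for Tac2, -3.90 for Agtr2, -1.69 for Cenpe, -1.38 for Bub1 and -1.25 for Kif11. Blood and neighbouring organ genes had 1.99 for Hbb-bh1, -1.62 for Alas2, -1.58 for Coro1a, -2.31 for Fgg, -3.11 for Serpina1c and 1.23 for Vil1. The others were 3.97 for Pdia2, 3.03 for Hsd3b6, 1.26 for Hmga2, -1.11 for Rimklb, -1.57 for Sox11, -1.59 for Hspb1, -2.02 for Stxbp4, -2.97 for Zfp141, -3.11 for Serpina1c, -3.29 for Kynu and -3.48 for Zfp985.

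The 2577 probe sets without a single gene symbol entered none of the comparisons as reported. They were fitted only together with all other probe sets. Called among them were 1157 for the mean sort difference, 1024 for the change in FVF+, 389 for the change in FVF- and 403 for the interaction.

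Acinar genes rose in FVF- with a median of 1.09 log2 units, and a candidate explanation is carry-over of FVF+ cells past the sort gate, which should bring hormone and endocrine genes in the same share. The share was measured in 3 ways, each chosen, with its minimum, after values had been seen: as the rise in FVF- over the rise in FVF+ among genes that rose by 2 or more log2 units in FVF+ (medians on E15.5 replicates 1, 2 and 3 of 3.90, 5.03 and 11.6% for 14 acinar genes against 0.131, 1.56 and 0.346% for 8 hormone and endocrine genes), as the rise over the FVF+ level (3.76, 5.43 and 9.14% against 0.281, 2.69 and 0.460%), and as the level over the FVF+ level among genes at least 4 log2 units above FVF- E12.5 (6.87, 9.03 and 14.7% against 4.46, 5.81 and 4.41%). Carry-over of FVF+ cells of every kind is argued against on replicate 3. There the lower quartile of acinar genes lay above the upper quartile of the others by each measure (9.27 against 1.06%, 7.82 against 1.51%, and 11.03 against 5.58%). Levels of genes only 2 log2 units above FVF- E12.5, where signal of E12.5 alone can exceed these shares, overlapped on it (11.9 against 14.8%). On replicate 1 the quartiles also lay apart by each measure (2.54 against 0.474%, 2.11 against 1.12%, and 5.75 against 4.90%). Levels on replicate 1 overlapped at 2 and at 3 units, however (6.19 against 14.4% and 6.16 against 7.26%). Since saturation also stayed open on replicate 1, carry-over cannot be told apart there. Saturation of the array is argued against on replicate 3, where acinar genes with FVF+ means under 13 had a median of 11.1% and lower quartiles of 9.20, 7.19 and 11.01%, and cannot be told apart on replicate 1 (median 3.89%, lower quartiles of 2.31, 1.99 and 4.87%, the last just under the 4.90% of the others), nor can carry-over on replicate 2 (lower quartile of 2.86% against an upper quartile of 5.10%). Epithelial, progenitor and ductal genes also rose in FVF- over these days, as carry-over would bring, and were not part of these shares. The argument above thus concerns only carry-over that holds hormone and endocrine cells in their FVF+ share. No test separated acinar cells in the FVF- gate from free acinar RNA, and a change of FVF- cells with embryonic day stayed open.

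From E14.5 to E15.5, FVF+ cells had 4931 calls of which 170 were of at least 2-fold, and medians over 5 equal groups of genes ordered by mean level were 0.14, 0.23, 0.03, -0.09 and -0.14, with 0.07, 0.10, -0.01, -0.09 and -0.11 in FVF- for the same step. A shift that depends on the expression level could account for part of this: after cyclic loess normalization 2781 calls, 56.4%, were lost or turned. In these genes the median absolute change went from 0.36 to 0.19 with a median SE of 0.10 before and after, so the calls ended because the changes shrank. Of the calls of at least 2-fold, 96.5% (164) were still called in the same direction. With medians of -0.14 to 0.23, the shift was too small to make changes of that size. The share kept thus follows from the size of the shift and is no separate evidence on the cause of these calls. Cyclic loess would also remove a biological change that follows the level, and embryonic day itself stayed open for all of the calls.

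At E14.5, FVF+ replicate 2 and FVF- replicate 1 deviated from their group means in a shared way, with an r of 0.58 across genes, which are not independent replicates, and both had the lowest signals of their groups for the Y-linked Eif2s3y (8.39 against 9.23 and 9.96 in FVF+, 8.02 against 8.78 and 9.49 in FVF-) and Uty and for Xist. Older embryos may account for part of the deviation of the FVF+ array, which correlated across genes with the FVF+ changes to E15.5 from E12.5 and from E13.5 at 0.59 and 0.55, while for the FVF- array age cannot be told apart from other origins, with correlations of 0.07 and 0.29 with these changes in FVF- and a second principal component of 22.0, against 7.8 and 1.4 on its group mates and 14.4 to 18.8 at E15.5. On the fourth component, with 3.1% of the variance, the FVF+ and the FVF- array lay at -23.2 and -26.5 and all others at -11.5 or above. The E15.5 arrays of both sorts lay between -4.5 and 18.2 on it. Components are uncorrelated by construction, and the second broadly followed the days. The fourth thus cannot show whether what the arrays share ran towards E15.5. On the second, the FVF+ array lay at 27.5, against 2.8 and -4.2 on its group mates and 35.3 to 39.2 at E15.5. FVF+ cells in the FVF- array cannot be told apart from another origin, since progenitor and epithelial genes had median deviations of -0.16 and -0.06 on it, between those of -0.50 and -0.58 on replicate 2 and of 0.52 and 0.55 on replicate 3. A shared effect of gene length cannot be told apart from others, with rho of -0.15 and -0.29 across genes on the FVF+ and the FVF- array. Apart from age and a different mix of male and female embryos, no biological explanation was examined. Such a mix would move Xist and the Y-linked genes in opposite directions. Both were lowest on these arrays instead, with Xist at 12.29 against 12.44 and 12.39 in FVF+ and at 11.04 against 12.56 and 11.79 in FVF-. These values argue against a different mix alone as the origin of what the arrays share.

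For the mean sort difference, 1 of 100 splits of the arrays within days, the real one, gave as many genes as the 10744 called, and the highest other gave 3601. No other split drawn reached this number, so chance is an unlikely origin of the number of calls. The splits do not speak to single genes. With 3 arrays against 3 there were 10 splits, too few for a share under 0.05, and in each case 1 split, the real one, gave as many genes: 8604 and 215 in the highest other split for the sorts at E14.5, 8478 and 0 for the sorts at E15.5, 9048 and 0 for E15.5 against E12.5 in FVF+, 4931 and 2 for E15.5 against E14.5 in FVF+, and 1253 and 6 for the same step in FVF-.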

How the results depend on the processing

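Cyclic loess normalization and leaving out both E14.5 arrays that stood apart were chosen after seeing the data. Counts are of called genes, and unless stated the cause of a change was not tested.

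With a 2-fold threshold, which by construction lowers counts, the sorts differed in 2284 genes for the mean, 2235, 2158, 2780 and 2598 at E12.5 to E15.5, E15.5 against E12.5 gave 1040 in FVF+ and 641 in FVF-, the daily steps 0, 300 and 170 in FVF+ and 61, 164 and 51 in FVF-, and the interaction 1101. Without dim genes, where fewer genes were tested, FVF+ E15.5 against E12.5 gave 5945, its first step 0, its last step 2491, 738 up and 1753 down, and the interaction 2497. The first FVF+ step, 1 gene as reported, gave 2 with all probe sets, 2 with median centring, 4 with quantile normalization, 4 with cyclic loess, 116 with array weights, 0 when fitted alone, 0 with a fixed replicate block and 9 with a term for letter-coded arrays. Quantile normalization gave 2889 for the last FVF+ step, and cyclic loess 2721 and, in FVF-, 625. Array weights gave 3366 and 7880 for the later FVF+ steps, 119 and 334 for the earlier FVF- steps and 6009 for the interaction. Fitted alone, the later FVF+ steps gave 799 and 2936, and the FVF- steps 1, 0 and 1. The letter-code term gave 127 for the middle FVF+ step and, for the earlier FVF- steps, the same counts as leaving out FVF- E13.5 replicate 2. Without both E14.5 arrays the middle FVF- step gave 880.

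In the mean sort difference, the changes from E12.5 to E15.5 and the interaction, the direction of a list test turned from downward by camera to upward by fry for mesothelium (0.12) and basement membrane (0.23) in FVF+ over time and red blood cells in the interaction (0.09), and from upward to downward by camera with median centring for immediate early genes in the interaction (0.17), with these medians above 0 in both. In the other comparisons fry turned upward for Notch genes at E13.5 (0.08) and in the first FVF+ step (0.04) and for epithelial (0.06), ductal (0.02) and neural crest genes (0.10) in the last, and downward for acinar genes in the first FVF- step (-0.10). None of these was called. Genes not called also changed sign: Krt19 between the sorts was -0.00 with quantile normalization, -0.01 with array weights, -0.04 without E13.5, -0.04 with cyclic loess, and -0.11 and -0.02 without FVF- E13.5 replicate 2 and FVF+ E14.5 replicate 2 (-0.11 to 0.19 over arrays left out). Foxa2 over time in FVF- was -0.01 with median centring, -0.03 with quantile normalization, and 0.00 and -0.08 without FVF- E12.5 replicate 1 and FVF- E15.5 replicate 2 (-0.08 to 0.21), and in FVF+ 0.00 without E15.5 replicate 1 (-0.25 to 0.00). Gcg over time in FVF+ was 0.02 with cyclic loess and 0.04 without E12.5 replicate 1 (-0.19 to 0.04). Over all genes named in the text and all settings except the 2-fold threshold, 5400 values were the same in direction and call, 138 were no longer called, 4 became called and 13 changed sign.

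Leaving out 1 array at a time gave 10190 to 10936 for the mean sort difference, 4701 to 6503, 4389 to 5476, 7530 to 8850 and 7501 to 7943 for E12.5 to E15.5, 7090 to 8243 for FVF+ and 1995 to 3372 for FVF- over time, 0 to 128, 555 to 1664 and 2222 to 5687 for the FVF+ steps, 4 to 413, 33 to 2894 and 298 to 1069 for the FVF- steps, and 1818 to 3443 for the interaction. Where 1 array was left in a group, it was assumed to vary like the other groups. Counts moved by more than 1.5 times without FVF- E12.5 replicate 1 (1995 over time, 49 in the first step) or 2 (2043, 4, and 1818 for the interaction), FVF- E13.5 replicate 1 (72 and 2894 in the first steps) or 2 (413 and 33), FVF- E14.5 replicate 1 (423 in the middle step) or 3 (669 in the last), and FVF- E15.5 replicate 1 (298) or 3 (710). In FVF+ they did so without E12.5 replicates 1, 2 and 3 (128, 4 and 3 in the first step), E13.5 replicate 1 (2 and 849 in the first steps) or 2 (0 and 555), E14.5 replicates 1 and 3 (2768 and 2222 in the last step) or 2 (1109 in the middle step), and E15.5 replicates 1 and 3 (3075 and 2975 in the last step).

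No label says that replicate numbers pair the sorts, and residuals of arrays with the same number correlated across genes at -0.37 to 0.49. As a random block, day and replicate number had a consensus correlation of 0.012, with every count within 1.5 times that reported. As a fixed block, which leaves 6 residual degrees of freedom, they gave 2392 for the interaction. Genes with a dim signal limit what an array can show: 11407 of 19296 genes passed the filter on it.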

Other observations

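Of the X-inactivation and Y-linked list, 4 of 5 members were measured. Xist lay between 11.04 and 13.60 and the Y-linked Eif2s3y between 8.02 and 10.42 over the 21 arrays. In FVF+, Eif2s3y fell by 1.13 between E12.5 and E15.5, Uty by 0.91 and Kdm5d by 0.89, all called by limma, while none of the 4 was called in FVF- or between the sorts.

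The embryonic globin gene Hbb-y lay at 11.18 on FVF+ E12.5 replicate 1 and at 11.40 and 11.01 on the FVF+ E13.5 arrays, and between 7.31 and 8.64 on the other FVF+ arrays. Gcg on FVF- arrays ranged from 8.53 on E15.5 replicate 1 to 11.76 on E15.5 replicate 2. Within the FVF- E14.5 group, progenitor and epithelial genes had median deviations from the group mean of 0.52 and 0.55 on replicate 3 and of -0.50 and -0.58 on replicate 2.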
